A study of Mus musculus with 14 samples.

How the data were processed

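The series holds 14 mouse bone marrow samples made by CITE-seq, a method that counts messenger RNA and antibody-derived tags (ADT, DNA barcodes carried by antibodies) in the same droplets. Per the labels, marrow of C57BL/6 mice was enriched with CD117 beads and sorted with a modified gate for granulocyte-monocyte progenitors, and 10000 cells per sample were loaded on the 10x Genomics platform. An mRNA and an ADT library came from each of 6 captures, 12 samples in all, 1 capture per genotype. The mixed-genotype capture of Ly6g-high cells, 2 further samples, was not analysed here. The labels give read counts of 373 to 449 (in units of 1e6) for these libraries.

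The deposited matrices hold counts, as whole-number UMIs (unique molecular identifiers) per gene and barcode, for 28692 genes. The submitters' processing notes name Cell Ranger, with no version, and the mm10 genome build. The deposited ADT tables hold raw tag counts per cell for 13 antibodies, and the tool that counted the tags is not given in the sources used here. The authors' cluster files assign each cell to 1 of 20 named clusters, and how the clusters were called is not given in the sources used here. Cluster names are printed as the authors gave them. Cells were used when they had both a count column and a cluster call.

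The labels of 2 captures conflict. The sample whose record gives R412X-R412X lists files named R412X-Irf8, and the sample whose record gives R412X-Het with Irf8+/- lists files named R412X-R412X. These captures are called the library filed as R412X-Irf8 and the library filed as R412X-R412X, no genotype is asserted for either, and they were never averaged. By either reading both carry R412X and a second altered allele. The K403R record gives K403R and its files are named K403R-Het, so its zygosity is not settled here. The K403R capture is also labelled female and the others male, so sex and genotype cannot be separated there.

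With 1 library per genotype no test was possible, and cells were not used as replicates. Values stand side by side with 95% intervals that cover counting error only: exact Clopper-Pearson intervals for shares of cells, log-normal intervals for ratios of shares, exact Poisson intervals for UMI sums, and Fay-Feuer gamma intervals for weighted sums. For ratios of gene levels, bounds set the lower end of 1 interval against the upper end of the other. These bounds are wider than a 95% interval. Clusters were also summed into classes by name: neutrophil (proNeu-1, proNeu-2, preNeu-1, preNeu-2, preNeu-3, immNeu), monocyte (MDP, MP, cMoP, Mono), progenitor (HSCP/MPP, Multi-Lin-1, Multi-Lin-2), dendritic (DC) and other lineages. The names were checked against marker genes: 7 clusters had, in at least 1 library, more markers of another class than of their own among their top 10 genes. These were MDP (in 5 libraries), proNeu-2 and Multi-Lin-2 (4 each), HSCP/MPP, Multi-Lin-1 and proNeu-1 (2 each) and Mono (1). For proNeu-1 and proNeu-2 it was 1 marker, Vcam1 of the macrophage set, against 0 of neutrophils. Tags of its product CD106 took 12.2% in the neutrophil class of wild-type and 1.13% in the monocyte class. Vcam1 therefore does not set these 2 clusters apart from neutrophils here. For MDP it was Flt3 of the dendritic set against 0 of monocytes, with Dntt of the lymphoid set added in 1 library.

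Expression was summed over cells per cluster and divided by all UMIs of those cells on a scale of 1e6 (CPM). To compare libraries that hold different mixtures of cells, the CPM of each cluster was averaged with the wild-type cluster shares as weights, over clusters with at least 30 cells in both libraries; this is called wild-type cluster composition. It covered 14 clusters for Gfi1+/-, 13 for K403R, 11 for R412X-Het and 15 for each of the libraries with conflicting labels. In R412X-Het, preNeu-1, preNeu-2, preNeu-3 and immNeu had too few cells, so that 60.5% of wild-type cells were covered, against 95.8% to 97.5% in the other comparisons. Of 21 gene lists, 1 held sex-linked genes and served to check labels and to leave genes out; the other lists were described by the median log2 ratio of members with at least 20 UMIs, the percentile of that median among 10000 random lists matched on size and mean expression, and the number of members at least 1.5-fold higher or lower. The lists hold genes of primary granules, secondary granules, late neutrophils, monocytes, dendritic cells, stem and progenitor cells, targets repressed by Gfi1, transcription factors of granulopoiesis, the unfolded protein response, apoptosis and p53, S phase, G2/M phase, interferon response, immediate early genes, basophils and mast cells, eosinophils, erythroid and megakaryocytic cells, lymphoid cells, marrow macrophages and niche, and mitochondrial transcripts.

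Named genes were, for each mutant library, the 10 largest and 10 smallest CPM ratios to wild-type at wild-type cluster composition. Genes with at least 100 UMIs over both libraries were ranked. Genes of the sex list, ribosomal protein and mitochondrial genes and gene models without a name were left out. Other genes on the sex chromosomes stayed in, among them Mid1, Xlr3b and Xlr on X and Erdr1 on Y. Gfi1 and Irf8 were named in every library, as were the 2 members with the largest and the 2 with the smallest ratio of a list where the list is described, and any gene among the 10 in 3 or more libraries. Not every gene that the rule names is printed. Gene positions came from GENCODE M21.

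Doublets were called with Scrublet in scanpy 1.11.5 and left in; an alternative left them out. Calls ranged from 7 cells in the library filed as R412X-Irf8 to 74 in Gfi1+/-, and the method separated few cells in the former library (0.154%) and in R412X-Het (0.401%). The other alternatives set before the data were examined were a filter of at least 2000 UMIs and under 10% mitochondrial UMIs, other lineages out of the denominator, reassignment of every cell to the wild-type cluster centroid with the highest correlation, TMM scaling, median-of-ratios scaling, no low-count filter (with 0.5 UMI added), a filter of at least 200 UMIs, equal weight per cluster, no composition adjustment, equal weight per cell (each scaled to 10000 UMIs), thinning every cell to 2000 UMIs, Gfi1+/- as the reference, and for tags the centred log ratio and the median count. Further alternatives were chosen after seeing the data: counting cells that had tags and a cluster but no count column, leaving out immNeu, counting IG2 as monocyte or as neutrophil, reassignment without genes of the neutrophil, monocyte, dendritic and Gfi1-repressed lists, leaving out the 7 clusters with markers of another class, counting shares among cells outside the neutrophil clusters, and leaving out genes for which 1 cell gave at least 20% of the UMIs of either library compared, where that library had at least 15. As a level of free RNA, genes read in early neutrophil clusters were also counted in Eryth and Meg cells. The gene lists, classes and named-gene rule were also set before the data were examined.

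The composition adjustment was tested on simulated data, in which wild-type rates were drawn at each mutant library's cluster mixture and genes were changed by known folds. Genes changed 4-fold were recovered at a median of 3.97 to 3.99 across the 5 comparisons, and genes set to 0.25 at 0.244 to 0.250. Unchanged genes passed 1.5-fold in 0.339% to 1.86% of cases with the adjustment and in 0.438% to 7.14% without it. The simulation held counting error only and used the same clusters to draw and to adjust. Changes in free RNA, shifts within clusters and differences between cells or animals were absent, so it gives no error rate for them. Tags were compared as shares of all tags of a library or class, because staining and tag depth differed between captures. Only cells with counts and a cluster call entered these shares. Tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16.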

Results

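Bone marrow progenitors of 6 genotypes were compared, with 1 capture per genotype, so no value has a replicate and every interval covers counting error only. The study concerns neutropenia, a shortage of neutrophils, in mice with altered Gfi1, a zinc finger repressor of transcription needed for neutrophil development. The captures were wild-type, Gfi1+/-, K403R (whose files are named K403R-Het while the sample record gives K403R, so that zygosity is unclear), R412X-Het, and the 2 libraries with conflicting labels, filed as R412X-Irf8 and as R412X-R412X. Irf8 is a transcription factor needed for monocytes and dendritic cells. All cells passed a CD117 bead enrichment and a modified progenitor gate, so shares describe the gated cells and not whole marrow.

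Cells with counts and a cluster call numbered 3804 in wild-type, 4090 in Gfi1+/-, 1805 in K403R, 4220 in R412X-Het, 4532 in the library filed as R412X-Irf8 and 5216 in the library filed as R412X-R412X. Total UMIs were lowest in K403R (30251212) and highest in the library filed as R412X-R412X (74836926). Median UMIs per cell lay between 14082 in Gfi1+/- and 16571 in K403R, and median mitochondrial UMIs between 3.04% and 3.45%. Median antibody tags per cell differed more, from 190 in R412X-Het to 780 in K403R.

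Gfi1 RNA was higher in all 5 mutant libraries than in wild-type, by 2.27-fold to 4.90-fold at wild-type cluster composition. Gfi1 (ENSMUSG00000029275; mm10 chromosome 5, 107716657 to 107726036, minus strand, 7 exons) stood at 67.1 CPM (64.9 to 69.4) in Gfi1+/- against 28.8 (27.5 to 30.3) in wild-type, a ratio of 2.33, and at 65.6 CPM (62.6 to 69.1) in K403R, a ratio of 2.27 to wild-type and 0.980 to Gfi1+/-. The ratio was 4.47 in R412X-Het, with 148 CPM (142 to 153) against 33.1 (31.4 to 34.9) over its 11 clusters. It was 4.90 in the library filed as R412X-Irf8 and 3.42 in the library filed as R412X-R412X. Within proNeu-1 Gfi1 ratios were 2.46 (2.11 to 2.88), 2.34 (1.957 to 2.81), 5.09 (4.40 to 5.90), 5.39 (4.67 to 6.23) and 3.26 (2.83 to 3.76) in the same order. In Eryth cells, the level against which free RNA was read, Gfi1 had 0 to 15.6 CPM in the mutant libraries and 3.06 in wild-type, far under the proNeu-1 level of 70.9 CPM in wild-type and 166 to 382 in the mutants. The counted tags lie at the 3′ end, and the last part of the transcript (107716657 to 107717739) is untranslated, so they do not tell altered from unaltered alleles. In the annotated protein of 423 residues, the positions that the allele names give hold glycine and leucine, and lysine and arginine stand 1 position further on, at 404 and 413 in exon 7. The numbering of the allele names therefore differs from this annotation.

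Irf8 RNA was far higher in the library filed as R412X-Irf8 and close to wild-type over all covered clusters in Gfi1+/- and K403R. At wild-type cluster composition Irf8 (ENSMUSG00000041515; mm10 chromosome 8, 120736358 to 120756694, plus strand, 9 exons) stood at 321.5 CPM (313 to 331) in that library against 99.7 (97.3 to 102) in wild-type, a ratio of 3.22. Ratios were 0.986 in Gfi1+/-, 1.09 in K403R, 1.35 in R412X-Het and 1.45 in the library filed as R412X-R412X. Within proNeu-1 Irf8 had 11.6 CPM (9.08 to 14.7) in wild-type, 14.8 (11.9 to 18.2) in Gfi1+/-, 22.05 (17.3 to 27.7) in K403R, 79.9 (71.6 to 88.9) in R412X-Het, 244.7 (230.4 to 259.6) in the library filed as R412X-Irf8 and 56.7 (51.5 to 62.3) in the library filed as R412X-R412X. In Eryth and Meg cells, read as the level of free RNA, Irf8 had 5.73, 8.09, 15.3, 13.8, 42.6 and 12.7 CPM in the same order, so that proNeu-1 stood over 4 times that level only in the R412X libraries. In cMoP the levels were 384 CPM in wild-type, 411.7 in R412X-Het, 944 in the library filed as R412X-Irf8 and 532 in the library filed as R412X-R412X. Without the composition adjustment the Irf8 ratio was 4.81 in the library filed as R412X-Irf8 and 2.06 in R412X-Het, where monocyte clusters were enlarged.

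**Figure D1:**
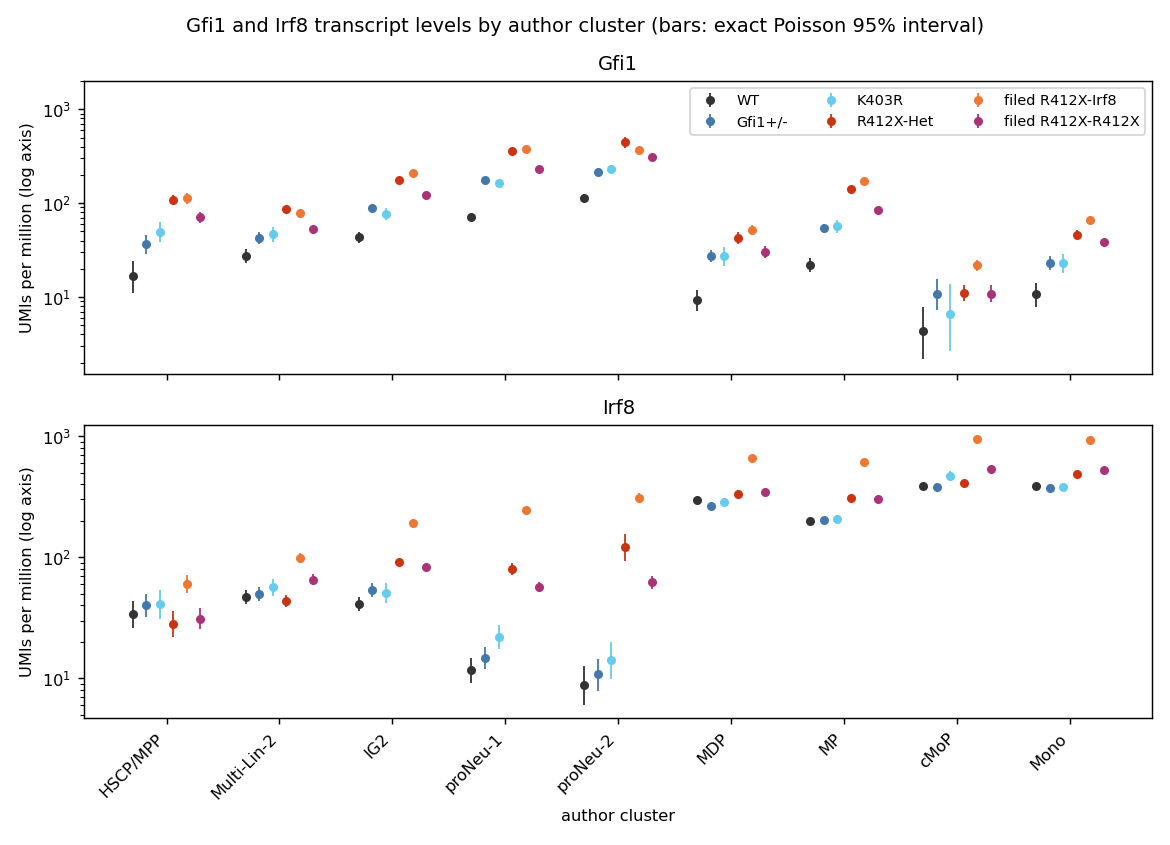
Gfi1 and Irf8 level per author cluster (CPM, log axis) in the 6 libraries, with exact Poisson 95% intervals. Gfi1 in proNeu-1 ran from 70.9 CPM in wild-type to 382 in the library filed as R412X-Irf8, and Irf8 in proNeu-1 from 11.6 to 244.7.

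Gfi1+/-, a label that gives 1 wild-type allele although Gfi1 RNA was 2.33-fold higher than in wild-type, was compared with wild-type first. It differed from wild-type mainly at the end of the neutrophil series: immNeu made up 3.69% of cells (3.14 to 4.32) against 7.26% (6.45 to 8.13), a ratio of 0.509 (0.419 to 0.617). With the cells that have a cluster call but no counts included, an alternative chosen after seeing the data, the immNeu ratio was 0.635 (0.545 to 0.740). Such cells, whose source was not tested, numbered 149 in Gfi1+/- and 152 in wild-type, and near-equal numbers lift a low ratio. Mono was 1.37-fold larger (1.16 to 1.62). IG2 was smaller (ratio 0.812, 0.681 to 0.968). The other neutrophil clusters had ratios from 1.01 in proNeu-1 to 1.16 in proNeu-2, and the summed neutrophil class stood at 48.7% against 49.0%. The early neutrophil serine protease gene Elane was 1.31-fold higher within proNeu-1 (1.28 to 1.34), and Mpo, for myeloperoxidase, stood at 1.01 (0.979 to 1.04).

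In gene groups at wild-type composition, Gfi1+/- stayed near wild-type: the median over all genes was 0.01 on the log2 scale. The late neutrophil list had a median of -0.11 (percentile 0.12 of random lists, 1 of 18 members at least 1.5-fold lower), with Retnlg at -1.07, Fpr1 at -0.51, and Stfa2 at 0.58 and Stfa2l1 at 0.29 at the other end. The unfolded protein response list had -0.15 (percentile 0; no member past 1.5-fold), with Asns at -0.55 and Hyou1 at -0.40 lowest and Ppp1r15a at 0.44 and Dnajb9 at 0.18 highest. Within proNeu-1 and proNeu-2 this list stood at -0.40 in each. Stem and progenitor genes stood at 0.14 (percentile 100; 1 higher and 1 lower of 27), with Egr1 at 0.64, Mn1 at 0.56, Procr at -0.38 and Ifitm1 at -0.74. The Gfi1-repressed list had 0.06 (percentile 93.5; 4 higher and 1 lower of 21) and 0.35 within proNeu-1 (for the 7 of 13 members above the Eryth and Meg level in both libraries, 0.14 before and 0.12 after it was subtracted), with Gfi1 at 1.22, Mycn at 0.69, E2f5 at -0.10 and Csf1 at -0.77. Monocyte genes (0.06), primary granule genes (0.06), secondary granule genes (0.01) and granulopoiesis transcription factors (0.02, 2 of 17 higher) moved little. Lymphoid genes had 0.54 (percentile 100; 5 of 11 higher), a list of few counts in which Iglc1 at 3.35 (27 UMIs against 4) and Ccl5 at 1.37 (31.4% of its UMIs in 1 cell) were highest and Vpreb1 at -0.27 and Ighm at -0.03 lowest.

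The largest single-gene ratios in Gfi1+/- were Mid1 (3.86; 15.4 CPM, 14.3 to 16.6, against 3.99, 3.49 to 4.58), Xlr3b (3.54), Hist1h4m (3.05) and Gfi1 itself. Mid1 (ENSMUSG00000035299) lies on mm10 chromosome X, 169685199 to 170005736. Among the smallest were Mtus2 (0.349), Loxl2 (0.413), Asprv1 (0.473) and Retnlg (0.476; 411.9 CPM, 399.8 to 424, against 866, 853 to 879), a gene of late neutrophils. A single cell gave at least 20% of the UMIs for 4 of the 10 highest genes (BC100530, Stfa3, Ccl5 and H2-Aa) and 2 of the 10 lowest (Cma1 and Ly6d), so those were not read as library differences.

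The K403R library was compared with wild-type in the same way. Among cells with counts its mixture differed most in immNeu, which made up 2.05% (1.45 to 2.81; 37 cells), a ratio of 0.283 (0.201 to 0.396). A further 98 immNeu cells of K403R and 100 of wild-type had no counts, and with them included the ratio was 0.728 (0.602 to 0.879). HSCP/MPP was 1.54-fold larger (1.22 to 1.93), Mono 1.45-fold (1.19 to 1.78), proNeu-2 1.33-fold (1.06 to 1.67) and preNeu-2 1.19-fold (1.01 to 1.41), and MDP was smaller (ratio 0.752, 0.619 to 0.913). Elane within proNeu-1 was 1.34-fold higher (1.31 to 1.38) and Mpo 1.17-fold (1.14 to 1.21). K403R was the only library labelled female, so sex and genotype differ together in each of its values.

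In K403R at wild-type composition, the late neutrophil list was lowest, with a median of -0.20 (percentile 0; 4 of 18 members at least 1.5-fold lower), led by Stfa2 at -4.29 and Il1b at -1.69, with Wfdc21 at 0.13 and Mmp25 at 0.11 highest. Primary granule genes had 0.17 (percentile 100, none of 16 past 1.5-fold), with Gstm1 at 0.46 and Elane at 0.42 highest and Calr at -0.24 and Trem3 at -0.20 lowest. Within proNeu-1 the summed primary granule list differed from wild-type in Eryth and Meg cells by 0.622 of its difference there. Its 16 members had a median of 0.13 before and -0.02 after the Eryth and Meg level was subtracted, so free RNA is not set apart for this list. Monocyte genes had 0.12, with Pld4 at 0.48 and Ctss at 0.41 highest and Ms4a4c at -0.20 among the lowest. Within proNeu-1 the monocyte list stood at 0.54 and the Gfi1-repressed list at 0.57, but the summed monocyte list differed from wild-type in Eryth and Meg cells by 0.514 of its difference in proNeu-1, and the 7 of 14 Gfi1-repressed members above that level in both libraries had 0.92 before and 0.19 after it was subtracted. Over all covered clusters the Gfi1-repressed list stood at 0.13, with Gfi1 at 1.18 and Mycn at 1.02 highest and Id2 at -0.20 and Id1 at -0.19 lowest. Stem and progenitor genes had 0.16, interferon genes -0.07 (5 of 25 lower), with Ifit3 at -1.29 and Ifit1 at -0.98 lowest, and secondary granule genes 0.07. With cells thinned to 2000 UMIs the interferon median was 0.0208, and without the composition adjustment the secondary granule median was -0.15. Erythroid genes had 0.82 (12 of 20 higher), with Hbb-bs at 8.33 and Hba-a1 at 8.06, and Eryth cells made up 1.55% against 0.789%. For each of these hemoglobin genes a single cell gave at least 20% of the UMIs.

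Single genes furthest above wild-type in K403R, beyond those resting on 1 cell, were Myl10 (6.36), Slc15a2 (4.21), Mid1 (3.65), Dynlt1b (3.24) and Sdsl (3.08). Myl10 (ENSMUSG00000005474; mm10 chromosome 5, 136693146 to 136701094) had 8.01 CPM (7.01 to 9.77) against 1.26 (0.953 to 1.68). With Gfi1+/- as the reference Mid1 had a ratio of 0.942, so its difference from wild-type was shared by both libraries. Furthest below, apart from genes resting on 1 cell, were Asprv1 (0.204), Tmem108 (0.287), Retnlg (0.437), Lect1 (0.451), Il1r1 (0.455) and Tesc (0.457). A single cell gave at least 20% of the UMIs for 5 of its 10 highest and 4 of its 10 lowest genes, the hemoglobin genes, Igkc, Jchain and Loxl2 among them.

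The comparison of R412X-Het with wild-type addresses what this mutant allele does to neutrophil formation. Neutrophil clusters past proNeu-1 were nearly empty: preNeu-3 held 20 of 4220 cells (0.474%, 0.290 to 0.731) against 639 of 3804 in wild-type (16.8%, 15.6 to 18.0), a ratio of 0.0282 (0.0181 to 0.0439). The ratio was 0.698 (0.588 to 0.828) in proNeu-1, 0.154 (0.105 to 0.226) in proNeu-2, 0.0926 (0.0545 to 0.157) in preNeu-1, 0.0524 (0.0335 to 0.0821) in preNeu-2 and 0.0425 (0.0244 to 0.0739) in immNeu. With cells that had no counts included the immNeu ratio was 0.378 (0.315 to 0.453) and the preNeu-3 ratio 0.0275 (0.0179 to 0.0424). Monocyte-lineage clusters were larger, with cMoP at 23.6% (22.4 to 24.96) against 4.81% (4.15 to 5.54), a ratio of 4.92 (4.23 to 5.72), MP at 2.46 (2.17 to 2.79) and Mono at 1.502 (1.28 to 1.77). IG2 was 1.92-fold larger (1.66 to 2.21) and HSCP/MPP 1.47-fold (1.21 to 1.77), while MDP was smaller (ratio 0.684, 0.587 to 0.796). Shares sum to a whole: among cells outside the neutrophil clusters, a denominator chosen after seeing the data, the ratio was 2.71 (2.34 to 3.14) for cMoP, 1.35 (1.199 to 1.53) for MP, 1.06 (0.920 to 1.22) for IG2, 0.828 (0.706 to 0.972) for Mono, 0.808 (0.672 to 0.973) for HSCP/MPP, 0.377 (0.325 to 0.437) for MDP and 1.151 (1.098 to 1.21) for the monocyte class. The summed neutrophil class was 7.51% against 49.0% (ratio 0.153, 0.137 to 0.171) and the monocyte class 57.6% against 27.6% (ratio 2.09, 1.97 to 2.21). With the 7 clusters that held markers of another class left out, an alternative chosen after seeing the data, the neutrophil ratio was 0.0436 and the monocyte ratio 3.40. That alternative dropped proNeu-1 and proNeu-2 for Vcam1 alone, so 0.0436 covers only the later neutrophil clusters. With IG2 counted as neutrophil, also chosen after seeing the data, the neutrophil ratio was 0.363.

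Cells that R412X-Het still placed in early neutrophil clusters carried more monocyte and primary granule RNA. The primary granule list within proNeu-1 had a median of 0.50 (7 higher and 1 lower of 16), and Elane was 2.22-fold higher (2.17 to 2.27), at 8528 CPM against 3840.1, with 181 CPM against 112 in Eryth and Meg cells. Mpo was 1.39-fold higher (1.34 to 1.43). The monocyte list within proNeu-1 had a median of 1.29 (percentile 100), and Irf8 there was 6.86-fold higher (4.86 to 9.80). Summed over the list, the difference from wild-type in Eryth and Meg cells was 0.0220 of that in proNeu-1, and for Irf8 it was 0.118. Klf4, a transcription factor of monocytes, had 4.05 CPM against 0.499 in proNeu-1, where the difference in Eryth and Meg cells was 0.484 of that, so free RNA is not set apart there. In proNeu-2, with 30 cells, Klf4 had 22.8 CPM (11.8 to 39.8) against 1.43 (0.465 to 3.34), and the difference in Eryth and Meg cells was 0.0805 of that. Csf1r, the receptor of the monocyte growth factor, had 15.7 CPM (12.2 to 20.02) against 4.32 (2.82 to 6.34) in proNeu-1, and 1.72 in Eryth and Meg cells. The Gfi1-repressed list had 0.78 within proNeu-1, and its 7 of 15 members above the Eryth and Meg level in both libraries had 1.86 before and 2.23 after it was subtracted. The top genes of proNeu-1 in 2 libraries and of proNeu-2 in 4, wild-type among the latter, held more markers of another class than of neutrophils. In each case this was 1 marker, Vcam1 of the macrophage set, against 0 of neutrophils. In R412X-Het the top genes of proNeu-2 held 3 neutrophil markers. These counts therefore do not bear on the monocyte RNA.

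At wild-type composition, which in R412X-Het leaves out preNeu-1 to preNeu-3 and immNeu, the median over all genes was 0.13 and the monocyte list 0.39 (percentile 100; 7 higher and none lower of 24), with Ctss at 1.51 and Cd68 at 1.11 highest and Ly86 at -0.50 among the lowest. Primary granule genes had 0.38 (6 higher and 1 lower of 16), with Ctsg at 1.12 and Elane at 1.06 highest and Fcnb at -0.61 and Hk3 at -0.14 lowest. The Gfi1-repressed list had 0.35 (3 higher and 2 lower of 20), with Gfi1 at 2.16 and Gfi1b at 1.64 highest and Ets1 at -0.76 and Csf1 at -0.60 lowest. Stem and progenitor genes had 0.26, with Ly6a at 1.75 and Procr at 1.19 highest and Hmga2 at -0.58 and Kit at -0.47 lowest. Apoptosis and p53 genes had 0.46 (percentile 100; 5 of 21 higher), with Pmaip1 at 1.31, Sesn2 at 0.93, Cdkn1a at -0.28 and Bcl2l1 at -0.19. Secondary granule genes had -0.29 (5 higher and 10 lower of 22), from Ly6g at -6.42 and Itgb2l at -6.35 to Mmp8 at 2.34 and Anxa1 at 1.27, and late neutrophil genes -0.52 (8 of 16 lower), with Retnlg at -5.79 and Stfa2l1 at -3.38. These granule RNAs were spread over unrelated wild-type cells: Camp had 831 CPM (735 to 936) in wild-type Eryth cells and 3.91 (0.473 to 14.1) in those of R412X-Het, and its adjusted wild-type level was 916 CPM. Their low ratios are therefore read as background, and with cells thinned to 2000 UMIs the list medians were 0.0416 and 0.0020. Without the composition adjustment they were -2.20 and -2.56, and the monocyte median was 1.08.

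The genes furthest above wild-type in R412X-Het, after those resting on 1 cell, were Socs3 (8.58; 8.14 CPM, 7.24 to 9.29, against 0.949, 0.635 to 1.39), a feedback inhibitor of cytokine signalling, Rhoj (7.29), Cdc42bpb (7.09), Lrig3 (6.93) and Myo18b (6.79). Socs3 (ENSMUSG00000053113) lies on mm10 chromosome 11, 117966079 to 117970047. Of the 10 lowest genes, Ly6g (0.0117), Itgb2l (0.0122), Ngp (0.0177), Retnlg (0.0181), Ltf (0.0212), Mmp9 (0.0432), Camp (0.0467), Orm1 (0.113) and Chil1 (0.116) are neutrophil granule or late neutrophil genes. In wild-type Eryth and Meg cells Ngp had 530 CPM and Ltf 67.3, against adjusted wild-type levels of 585 and 66.6. With preNeu-1 to preNeu-3 and immNeu left out, low ratios of such genes are read as background here too. A single cell gave at least 20% of the UMIs for 5 of its 10 highest genes and 2 of its 10 lowest, Retnlg and Cma1.

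The library filed as R412X-Irf8 held fewer late neutrophil cells and a larger cluster named Mono than wild-type. The top 10 genes of Mono held no marker of the monocyte list in wild-type, R412X-Het and both libraries with conflicting labels, 2 in Gfi1+/- and 4 in K403R. In the library filed as R412X-Irf8 they were plasma cell and hemoglobin genes. Genes resting on 1 cell were not left out of this ranking. It therefore does not settle what most of the 775 Mono cells of that library were. Its preNeu-3 share was 1.52% (1.19 to 1.92), a ratio of 0.0906 (0.0710 to 0.116), and ratios were 0.724 (0.613 to 0.854) in proNeu-1, 0.405 (0.314 to 0.523) in proNeu-2, 0.172 (0.117 to 0.255) in preNeu-1, 0.0878 (0.0625 to 0.123) in preNeu-2 and 0.116 (0.0826 to 0.162) in immNeu, or 0.381 (0.319 to 0.454) with cells that had no counts included. Mono made up 17.1% (16.0 to 18.2) against 5.68%, a ratio of 3.01 (2.61 to 3.48), cMoP 21.4%, a ratio of 4.45 (3.83 to 5.18), and MP 17.7%, a ratio of 2.28 (2.01 to 2.58), while MDP was smaller (ratio 0.811, 0.704 to 0.935). Among cells outside the neutrophil clusters these ratios were 1.73 (1.50045 to 1.99), 2.55 (2.20 to 2.96), 1.31 (1.16 to 1.47) and 0.465 (0.405 to 0.534). DC had 7 cells, 0.154% (0.0621 to 0.318) against 0.394% (0.221 to 0.650). The summed neutrophil class was 11.1% (ratio 0.226, 0.207 to 0.247) and the monocyte class 63.8% (ratio 2.31, 2.18 to 2.44); without the 7 clusters with markers of another class the ratios were 0.103 and 3.11, and with IG2 counted as neutrophil the first was 0.348. Elane within proNeu-1 was 2.54-fold higher (2.49 to 2.60) and Mpo 1.37-fold (1.33 to 1.41).

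In the library filed as R412X-Irf8 at wild-type composition, the monocyte list had a median of 0.60 (percentile 100; 13 higher and 1 lower of 24), with Irf8 at 1.69 and Ctss at 1.60 highest and Ly86 at -0.47 among the lowest, against 0.11 for all genes. Primary granule genes had 0.37 (6 of 16 higher), with Elane at 1.25 and Gstm1 at 1.24 highest and Fcnb at -0.21 and Calr at -0.07 lowest. Within proNeu-1 the monocyte list had 0.96 and the Gfi1-repressed list 0.90, and the summed monocyte list differed in Eryth and Meg cells by 0.0925 of its difference there. The 8 of 14 Gfi1-repressed members above the Eryth and Meg level in both libraries had 0.90 before and 1.00 after it was subtracted. Secondary granule genes had 0.01 (3 higher and 5 lower of 22), with Mmp8 at 2.36 and Chil3 at 0.79 highest and Ly6g at -2.23 and Orm1 at -1.28 lowest. Late neutrophil genes had 0.16 (4 of 18 higher), led by Stfa2 at 1.93 and Mmp25 at 1.01. Without the composition adjustment these medians were -1.88 and -1.77. Stem and progenitor genes had 0.38, led by Ly6a at 1.62 and Procr at 1.103, with Egr1 at -1.21 and Mn1 at -0.72 lowest. Rara, for retinoic acid receptor alpha, led the granulopoiesis transcription factors at 1.57 apart from Gfi1 at 2.29. The largest single-gene ratios after those resting on 1 cell were Ptgfrn (85.0, from 102 UMIs against 1; 1.00 CPM, 0.307 to 3.01, against 0.0118, 0.0003 to 0.199), Qpct (13.05), Myo18b (9.73) and Snx7 (8.77), and among the smallest were Tesc (0.0426) and Asprv1 (0.137). A single cell gave at least 20% of the UMIs for 6 of its 10 highest genes and 3 of its 10 lowest.

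The library filed as R412X-R412X held smaller shares of preNeu-1, preNeu-2 and preNeu-3 than wild-type and larger ones than R412X-Het. Its proNeu-1 and proNeu-2 shares were at wild-type levels, with ratios of 1.06 (0.916 to 1.23) and 1.04 (0.865 to 1.26), and ratios of the later clusters were 0.719 (0.574 to 0.902) in preNeu-1, 0.515 (0.440 to 0.604) in preNeu-2, 0.329 (0.288 to 0.375) in preNeu-3 and 0.0951 (0.0674 to 0.134) in immNeu, or 0.360 (0.303 to 0.427) with cells that had no counts included. Of the monocyte clusters cMoP, Mono and MP were larger and MDP was smaller (ratio 0.713, 0.619 to 0.821), with cMoP at 16.9% (ratio 3.52, 3.02 to 4.10), Mono at 9.43% (1.66, 1.42 to 1.94) and MP at 11.9% (1.54, 1.35 to 1.76). Among cells outside the neutrophil clusters the ratios of cMoP, Mono, MP and MDP were 2.44 (2.098 to 2.83), 1.15015 (0.990 to 1.34), 1.07 (0.939 to 1.21) and 0.494 (0.430 to 0.566). Meg was 3.18-fold larger (2.11 to 4.78) and HSCP/MPP 1.66-fold (1.39 to 1.98), and outside the neutrophil clusters their ratios were 2.20 (1.46 to 3.31) and 1.147 (0.963 to 1.37). The summed neutrophil class was 26.3% (ratio 0.538, 0.508 to 0.568) and the monocyte class 44.98% (ratio 1.63, 1.54 to 1.73). Elane within proNeu-1 was 2.66-fold higher (2.61 to 2.72) and Mpo 1.38-fold (1.35 to 1.42). The MP ratio was 0.941 when cells were reassigned without the neutrophil and monocyte genes, and the summed ratios were 0.369 and 2.30 without the 7 clusters with markers of another class, both alternatives chosen after seeing the data.

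In the library filed as R412X-R412X at wild-type composition, primary granule genes had 0.38 (percentile 100; 6 of 16 higher), with Elane at 1.28 and Gstm1 at 1.102 highest and Calr at -0.18 and Trem3 at -0.10 lowest, against 0.12 for all genes. Monocyte genes had 0.33 (7 of 24 higher), with Ctss at 1.38 and Cd68 at 1.18 highest and Ly86 at -0.37 and Mpeg1 at -0.21 lowest, and stood at 0.83 within proNeu-1, where the difference of the summed list in Eryth and Meg cells was 0.0981 of that in proNeu-1. The Gfi1-repressed list had 0.31 and, within proNeu-1, 1.06 (for the 9 of 16 members above the Eryth and Meg level in both libraries, 1.03 before and 0.59 after it was subtracted), with Gfi1 at 1.77 and Gfi1b at 1.27 highest and Csf1 at -1.12 and Egr1 at -0.99 lowest. Secondary granule genes had 0.21 (4 higher and 2 lower of 22), with Mmp8 at 2.18 and Chil3 at 0.96 highest and Ly6g at -1.41 and Orm1 at -0.64 lowest. Late neutrophil genes had -0.11, from Stfa2 at -3.53 and Stfa2l1 at -1.499 to Fpr1 at 1.31 and Slpi at 0.92, and without the composition adjustment these medians were -1.04 and -1.48. Erythroid and megakaryocytic genes had 1.02 (14 of 21 higher), led by Hbb-bs at 5.76 and Hba-a2 at 5.25, with 91.4% and 93.3% of their UMIs in a single cell. Among the largest single-gene ratios after those resting on 1 cell were Qpct (24.7; 10.0 CPM, 7.36 to 13.7, against 0.405, 0.255 to 0.672), Kcne3 (15.3), Lrig3 (9.65), Snx7 (9.14) and Tpm4 (5.42), and among the smallest were Tesc (0.0441), Asprv1 (0.184) and Smkr-ps (0.190). A single cell gave at least 20% of the UMIs for 7 of its 10 highest genes and 2 of its 10 lowest.

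**Figure D2:**
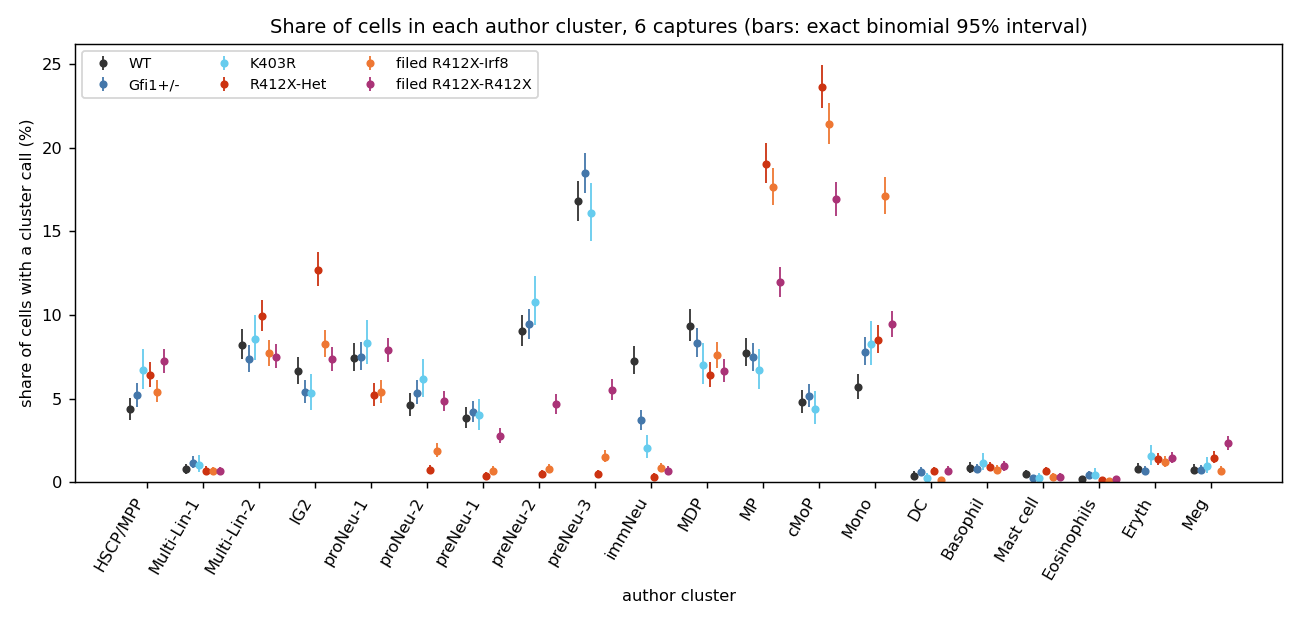
Share of gated cells per author cluster (percent) in the 6 libraries, with exact 95% binomial intervals. The preNeu-3 share was 16.8% in wild-type, 0.474% in R412X-Het, 1.52% in the library filed as R412X-Irf8 and 5.52% in the library filed as R412X-R412X, and the cMoP share 4.81%, 23.6%, 21.4% and 16.9%.

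Setting the mutants beside each other addresses how the models differ and whether a second altered allele shifts the R412X mixture. R412X-Het held 0.0256 (0.0165 to 0.0399) of the preNeu-3 share of Gfi1+/- and 4.58-fold (3.98 to 5.28) its cMoP share. K403R held 34.0-fold (21.7 to 53.3) the preNeu-3 share of R412X-Het and 8.65-fold (5.80 to 12.9) its proNeu-2 share. The library filed as R412X-R412X held 11.7-fold (7.42 to 18.3) the preNeu-3 share, 9.83-fold (6.24 to 15.5) the preNeu-2 share and 6.80-fold (4.66 to 9.90) the proNeu-2 share of R412X-Het, with a cMoP ratio of 0.716 (0.660 to 0.776). The library filed as R412X-Irf8 exceeded R412X-Het less, by 3.21-fold (1.956 to 5.28) in preNeu-3 and 2.64-fold (1.74 to 3.99) in proNeu-2, and its Mono share was 2.00-fold (1.78 to 2.26) larger. Between the libraries with conflicting labels, the one filed as R412X-R412X had 3.63-fold (2.80 to 4.70) the preNeu-3 share, 0.552 (0.496 to 0.613) of the Mono share and 4.47-fold (1.99 to 10.0) the DC share. Irf8 at wild-type composition in that library was 1.05 times that of R412X-Het, and in the library filed as R412X-Irf8 2.11 times.

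**Figure D3:**
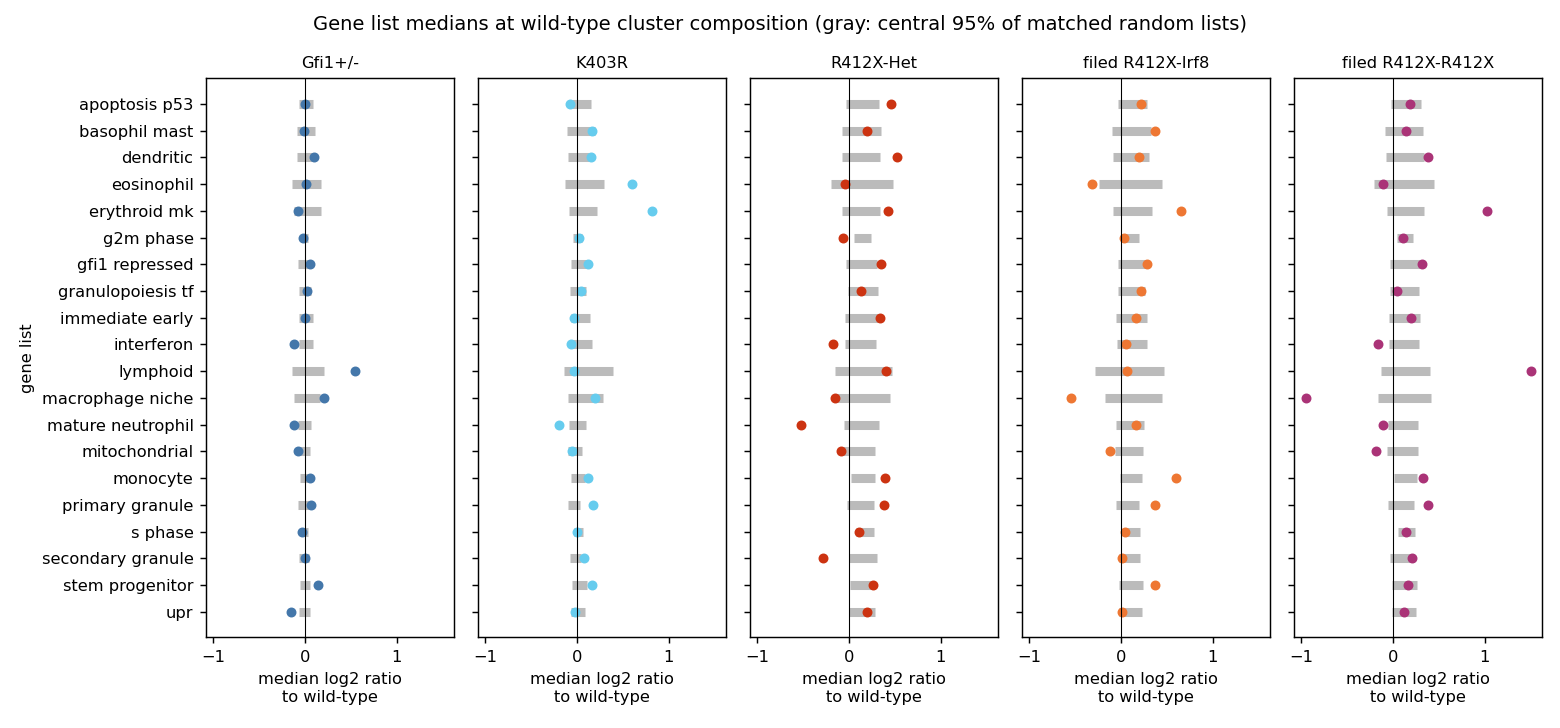
Median log2 ratio to wild-type of each gene list at wild-type cluster composition, for the 5 mutant libraries. The monocyte list ran from 0.06 in Gfi1+/- to 0.60 in the library filed as R412X-Irf8, and the primary granule list from 0.06 to 0.38.

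Several genes recurred among the largest ratios. Apart from genes resting on 1 cell, Snx7 and Lrig3 were among the 10 highest in all 3 R412X libraries, Tesc among the 10 lowest in K403R and the 3 R412X libraries, Asprv1 in the other 4 mutant libraries, and Smkr-ps in 3. In R412X-Het Asprv1 had too few UMIs to be ranked, 1 against 33. Snx7, a sorting nexin (ENSMUSG00000028007; mm10 chromosome 3, 117781647 to 117868936), had 12.9 CPM (11.4 to 14.5) against 2.20 (1.77 to 2.75) in R412X-Het. Tesc (ENSMUSG00000029359; mm10 chromosome 5, 118027743 to 118061878), for the calcium-binding protein tescalcin, had 0.855 CPM (0.239 to 2.80) in the library filed as R412X-Irf8 against 20.1 (18.6 to 21.6). Counting genes that rest on 1 cell, 10 genes recurred in 3 or more libraries, and unchanged libraries simulated against the same wild-type gave a mean of 0.2 and at most 1 in 20 runs. That simulation held counting error of the mutant libraries only, without UMIs gathered in 1 cell or differences between animals. Its rates were the wild-type counts themselves, so recurrence from counting error in the shared wild-type library could not arise. The numbers are therefore not on equal terms, and the low simulated count does not exclude that source. The 10 genes also included Hba-a1, Hba-a2, Hbb-bs, Cma1, Loxl2, Ly6d and Retnlg. All ratios share 1 wild-type library, whose own departures enter each of them.

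Among cells with counts, Ly-6G, a protein of maturing neutrophils, took 6.40% of all tags in wild-type, 3.34% in Gfi1+/-, 2.26% in K403R, 0.0431% in R412X-Het, 0.128% in the library filed as R412X-Irf8 and 0.382% in the library filed as R412X-R412X. Tagged cells without counts are left out of every share here: 150 in R412X-Het with a median of 123.5 Ly-6G tags, and 152 in wild-type with 208.5. Ly-6G shares that count them were not computed and would be higher. The neutrophil class holds different clusters in each library, mostly proNeu-1 in R412X-Het (219 cells) and mostly later clusters in wild-type, and within it Ly-6G took 11.2% in wild-type, 5.67% in Gfi1+/-, 3.90% in K403R and 0.406% to 0.872% in the R412X libraries. The tagged cells without counts, nearly all named immNeu or preNeu-3, are missing from this class. In the R412X libraries their median Ly-6G tags were 123.5, 127 and 133, against 6, 16 and 11.5 in immNeu cells with counts. Within preNeu-3 alone Ly-6G took 13.4% in wild-type, 9.37% in Gfi1+/-, 8.73% in K403R, 1.39% in the library filed as R412X-Irf8 and 2.04% in the library filed as R412X-R412X. CD11b, an integrin of myeloid cells, took 9.14% of neutrophil-class tags in wild-type, 2.05% in R412X-Het, 3.12% in the library filed as R412X-Irf8 and 7.52% in the library filed as R412X-R412X. CD106 took 12.2% of neutrophil-class tags in wild-type and 17.4% in K403R, 21.7% in R412X-Het, 19.9% in the library filed as R412X-Irf8 and 32.7% in the library filed as R412X-R412X; with median tags per cell the log2 ratio of CD106 in this class turned to -1.04 in R412X-Het. Within proNeu-1 alone CD106 took 7.73% in wild-type, 20.3% in R412X-Het, 18.3% in the library filed as R412X-Irf8 and 21.8% in the library filed as R412X-R412X. Ly-6C took 37.4% of all tags in wild-type, 46.5% in R412X-Het, 50.1% in the library filed as R412X-Irf8 and 21.1% in the library filed as R412X-R412X. In R412X-Het the higher share of Ly-6C did not hold otherwise, with log2 ratios of -0.01 by centred log ratio and -1.44 by median tags per cell. CD115, the product of Csf1r, was 22.6 times as large a share in the monocyte as in the neutrophil class of wild-type, 16.9 in Gfi1+/-, 14.6 in K403R, 3.79 in R412X-Het, 4.27 in the library filed as R412X-Irf8 and 9.24 in the library filed as R412X-R412X. Shares of a library's tags sum to a whole, so a lower share of 1 tag raises the others.

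**Figure D4:**
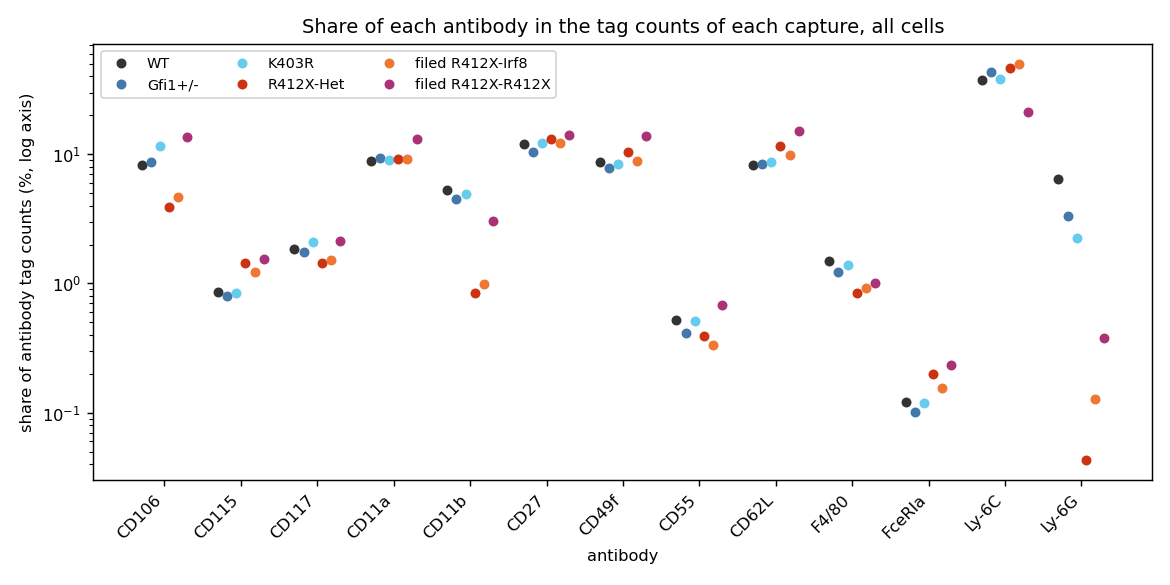
Share of antibody tags (percent of all tags of the cells with counts in a library) for each antibody in the 6 libraries. Tagged cells without counts are left out. Ly-6G ran from 6.40% in wild-type to 0.0431% in R412X-Het.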

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

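The search for cells outside the count matrices, the shares that include them and both Irf8 label tests were chosen after the results were seen, while the tests of the neutrophil share and of Elane were set before. Cells with a cluster call and antibody tags but no counts in the matrix are a signal in data not used in the comparisons. They numbered 152 in wild-type, 149 in Gfi1+/-, 147 in K403R, 150 in R412X-Het, 141 in the library filed as R412X-Irf8 and 161 in the library filed as R412X-R412X. Nearly all carried the names immNeu (100, 105, 98, 144, 131 and 148 cells) or preNeu-3 (52, 44, 49, 1, 5 and 9). Their median Ly-6G tags per cell were 208.5 in wild-type, 202 in Gfi1+/-, 161 in K403R, 123.5 in R412X-Het, 127 in the library filed as R412X-Irf8 and 133 in the library filed as R412X-R412X. The immNeu cells inside the matrices had medians of 188, 108, 141, 6, 16 and 11.5 in the same order. The cells outside the matrices were near equal in number in every library, although cells with counts ranged from 1805 to 5216. Counting them therefore lifts low immNeu ratios whatever the share in the gated cells. Their median tags per cell were 1786, 1721, 1810, 1374, 1303 and 1205 in the same order, against 421, 407.5, 780, 190, 470 and 245 in cells with counts. Where these cells came from was not tested, and the Ly6g-high mixed capture was not analysed here. Counting them gave immNeu ratios to wild-type of 0.635 in Gfi1+/-, 0.728 in K403R, 0.378 in R412X-Het, 0.381 in the library filed as R412X-Irf8 and 0.360 in the library filed as R412X-R412X, in place of 0.509, 0.283, 0.0425, 0.116 and 0.0951. The ratios of preNeu-3 stayed within their intervals, at 0.0275 in R412X-Het. Neutrophil class ratios were 0.209 in R412X-Het and 0.270 in the library filed as R412X-Irf8.

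The neutrophil class was smaller in all 3 R412X libraries, with ratios to wild-type of 0.153, 0.226 and 0.538. Against cluster calling as the source, reassignment of every cell to wild-type centroids, with and without the lineage genes, left the highest ratio at 0.571, under the bound of 0.67 set before. Against a higher UMI floor in the R412X libraries, their lowest UMI counts per cell were 3240, 3247 and 3334, all under the 3401 of wild-type, so that the highest of them left 100% of wild-type neutrophil cells, over the bound of 90% set before. Whether neutrophil cells of the R412X libraries held less RNA and were lost under a similar floor was not tested and stays open. The sort gate and the animal stay open too, and with 1 capture per genotype they cannot be told apart from the genotype.

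Elane was higher within proNeu-1 in all 5 mutant libraries, from 1.31-fold to 2.66-fold. Against free RNA from other cells, the difference in Elane between mutant and wild-type Eryth and Meg cells was at most 0.151 of that in proNeu-1, under the bound of 0.25. Against scaling by the library total, the lowest Elane ratio was 1.34 under median-of-ratios scaling within proNeu-1, over the bound of 1.2. With cells thinned to 2000 UMIs the Elane ratio was 1.21 (1.122 to 1.304) in Gfi1+/-, an interval that holds that bound, and 1.35 in K403R. With equal weight per cell it was 1.24 in Gfi1+/- and 1.40 in K403R. A shift of cells within proNeu-1 toward proNeu-2 was not tested. Wild-type Elane was 3840 CPM in proNeu-1 and 6134 in proNeu-2. The proNeu-1 levels of Gfi1+/- (5020) and K403R (5157) lay between these, so such a shift stays open there. Those of the R412X libraries (8528, 9771 and 10234) lay above both. Higher Elane in cells named proNeu-1 stands as a hypothesis for the R412X libraries, found and tested on the same data. Elane was not recomputed after reassignment of cells, so a different mix of cells under that name was not tested and stays open. The Elane difference did not extend to the primary granule list in all libraries. Within proNeu-1 the list had a median of -0.02 in Gfi1+/- and no member of 16 past 1.5-fold in K403R. Mpo in Gfi1+/- stood at 1.01. Differences between single animals and, in K403R, of sex stay open.

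Irf8 differed between the libraries whose labels conflict. If the file names gave the genotypes, the library filed as R412X-Irf8 would carry 1 altered Irf8 allele, yet its Irf8 RNA was 2.11 times that of R412X-Het at wild-type composition. If the sample records gave them, the library filed as R412X-R412X would, and its Irf8 RNA was 1.05 times that of R412X-Het. Both readings stay open and cannot be told apart, because tags from an altered allele may be counted at the 3′ end, so that the RNA level does not give the number of working alleles.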

How the results depend on the processing

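Alternatives that counted cells outside the matrix, left out immNeu, counted IG2 with a lineage, took neutrophil clusters out of the denominator, reassigned cells without the lineage genes, or left out clusters led by markers of another class or genes resting on 1 cell were chosen after seeing the data; the others were set before. No paired analysis was possible because each genotype had 1 library. Of 3456 values recomputed for 461 results, 2833 stayed within the spread of the reported value and 595 moved outside it. Another 28 were counted as changing direction. Only ratios and tags at least 1.5-fold from the reference, and list medians outside the central 95% of random lists, could be counted so. Other changes of direction are among the values that stayed or moved. For instance, HSCP/MPP in R412X-Het went from 1.47 to 0.808 with neutrophil clusters out of the denominator. The spread was the 95% interval for shares, the wider bounds for gene ratios, that of random lists for lists, and 1.5-fold for tags. The stricter filter on UMIs and mitochondrial share moved none of 87 values. Its UMI part removed no cell, because the lowest UMI counts per cell were 3240 to 3736, so it does not bear on depth. Leaving out doublets kept 395 values and turned 1. Of the class shares and of the shares of 13 clusters recomputed here, those at least 1.5-fold from wild-type that changed direction were of MP and Mono; with neutrophil clusters out of the denominator those of 2 smaller clusters turned too, Eryth to 0.961 in R412X-Het and 0.883 in the library filed as R412X-Irf8, and DC to 0.895 in R412X-Het. Depth limits the R412X-Het comparison, where clusters past proNeu-2 had too few cells to compare expression. Where a value below moved or turned, the cause was not tested.

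For the neutrophil share, ratios in K403R were 1.03 without immNeu and 0.892 without clusters led by markers of another class. In R412X-Het they were 0.363 with IG2 as neutrophil, 0.209 with cells outside the matrix, 0.181 after reassignment, 0.136 after reassignment without the lineage genes and 0.0436 without clusters led by other markers. In the library filed as R412X-Irf8 they were 0.348, 0.270, 0.263 and, for the last, 0.103. In the library filed as R412X-R412X they were 0.606 with IG2, 0.574 without immNeu, 0.571 after reassignment and 0.369 without clusters led by other markers. For the monocyte share, ratios in R412X-Het were 1.94 without immNeu, 2.28 with other lineages out of the denominator, 2.30 after reassignment, 2.39 after reassignment without the lineage genes and 3.40 without clusters led by other markers. In the library filed as R412X-Irf8 they were 2.10 with IG2 as monocyte, 2.16 without immNeu, 2.45 after reassignment without the lineage genes and 3.11 without clusters led by other markers, and in the library filed as R412X-R412X 1.53, 1.52, 1.77 and 2.30. With neutrophil clusters out of the denominator the monocyte ratios were 1.151 in R412X-Het, 1.32 in the library filed as R412X-Irf8 and 1.13 in the library filed as R412X-R412X, and that of Mono in R412X-Het turned to 0.828. The MP share of the library filed as R412X-R412X turned from 1.54 to 0.941 after reassignment without the lineage genes.

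With Gfi1+/- as the reference, which is a different comparison by construction, Gfi1 in K403R turned to 0.980 and to 0.951 within proNeu-1, and Gfi1 was 2.10 in R412X-Het, 2.11 in the library filed as R412X-Irf8 and 1.47 in the library filed as R412X-R412X. Cma1 turned to 7.83 in the library filed as R412X-R412X, Hba-a2 to 0.988 in R412X-Het, and Loxl2 and Mid1 to 1.12 and 0.942 in K403R. List medians turned to 0.0300 for apoptosis and p53 and 0.0336 for interferon in K403R, 0.0393 for G2/M phase and 0.0236 for mitochondrial transcripts in R412X-Het, and 0.0027 for late neutrophil genes in the library filed as R412X-R412X. In K403R late neutrophil genes had -0.0903 and primary granule genes 0.0712.

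Without the composition adjustment Gfi1 ratios were 3.66 in R412X-Het, 4.04 in the library filed as R412X-Irf8 and 3.07 in the library filed as R412X-R412X. Irf8 ratios were 1.04 in Gfi1+/-, 1.03 in K403R, 2.06 in R412X-Het, 4.81 in the library filed as R412X-Irf8 and 1.95 in the library filed as R412X-R412X. In the same order of 5 libraries, late neutrophil genes had -0.22, -0.32, -2.56, -1.77 and -1.48, secondary granule genes -0.11, -0.15, -2.20, -1.88 and -1.04, and monocyte genes 0.12, 0.0374, 1.08, 1.08 and 0.81. Interferon genes turned to 0.20 in R412X-Het and 0.14 in the library filed as R412X-R412X, and mitochondrial transcripts to 0.13 in R412X-Het and 0.0322 in the library filed as R412X-Irf8. Gfi1-repressed genes had 0.44 in the library filed as R412X-Irf8.

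TMM and median-of-ratios scaling each gave Gfi1 in R412X-Het 4.08 and Irf8 1.23 there, 1.33 in the library filed as R412X-R412X and 3.003 and 2.98 in the library filed as R412X-Irf8, and monocyte genes in R412X-Het 0.26. Thinning gave Gfi1 in the library filed as R412X-Irf8 4.45 and Irf8 in K403R 1.01; Gfi1-repressed genes had -0.0237 in Gfi1+/- and -0.31 in the neutrophil class of R412X-Het, interferon genes 0.0208 in K403R, and in R412X-Het late neutrophil genes 0.0020 and secondary granule genes 0.0416. With at least 200 UMIs these 2 lists had 0.00022 and -0.0253 in R412X-Het, Gfi1-repressed genes -0.17 in its neutrophil class, and macrophage and niche genes 0.0537 in the library filed as R412X-Irf8, where leaving out doublets gave 0.0212. Equal weight per cell gave late neutrophil genes in R412X-Het -0.16. With median tags per cell, CD106 and CD49f in the library filed as R412X-R412X turned to log2 ratios of -0.77 and -0.0431.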

Other observations

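The values in this part were set by the lists fixed before, except the search for Xist in wild-type, the genes near Gfi1 and the levels per cluster, which were chosen after the results were seen. Dendritic cell genes at wild-type composition had list medians of 0.52 in R412X-Het (percentile 99.96; 8 higher and 2 lower of 16) and 0.38 in the library filed as R412X-R412X (percentile 99.2; 6 higher and 1 lower of 15), against 0.13 and 0.12 for all genes. The medians were 0.10 in Gfi1+/- (3 of 15 higher), 0.15 in K403R (2 higher and 1 lower of 16) and 0.20 in the library filed as R412X-Irf8 (4 higher and 3 lower of 16). Dntt (1.27) and H2-Eb1 (0.78) led in K403R, Cd74 (1.39) and H2-Ab1 (1.21) in R412X-Het, Dntt (1.24) and H2-Ab1 (1.18) in the library filed as R412X-Irf8, and H2-Ab1 (1.25) and H2-Aa (1.22) in the library filed as R412X-R412X. Dntt counted as a lymphoid marker in the check of cluster names, so its ratios do not set dendritic cells apart. Batf3, a transcription factor of dendritic cells, was lower in K403R (-1.88) and in the library filed as R412X-Irf8 (-1.95).

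Genes of the cell cycle moved little. S phase genes had medians of -0.03, 0.00, 0.11, 0.05 and 0.14 in Gfi1+/-, K403R, R412X-Het, the library filed as R412X-Irf8 and the library filed as R412X-R412X, and G2/M genes -0.02, 0.03, -0.07, 0.04 and 0.11. In the same order, immediate early genes had 0.01, -0.03, 0.33, 0.16 and 0.19, with Hspa1a lowest at -0.68, -0.72, -0.94, -1.49 and -0.67. Apoptosis and p53 genes had 0.00, -0.07, 0.46, 0.22 and 0.19, and within Multi-Lin-2 0.13, 0.27, 0.48, 0.33 and 0.33. Granulopoiesis transcription factors had 0.02, 0.05, 0.13, 0.22 and 0.04. Interferon genes had -0.12, -0.07, -0.17, 0.06 and -0.16, unfolded protein response genes -0.15, -0.02, 0.19, 0.01 and 0.12, and mitochondrial transcripts -0.08, -0.05, -0.09, -0.11 and -0.19.

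Lists of other lineages rested on few counts. In the same order, basophil and mast cell genes had -0.01, 0.16, 0.19, 0.37 and 0.14, eosinophil genes 0.01, 0.60, -0.04, -0.32 and -0.11, macrophage and niche genes 0.21, 0.20, -0.15, -0.55 and -0.95, erythroid and megakaryocytic genes -0.08, 0.82, 0.42, 0.65 and 1.02, and lymphoid genes 0.54, -0.03, 0.41, 0.07 and 1.505. Cd5l (-1.955) and C1qa (-1.79) were lowest of the macrophage list in the library filed as R412X-Irf8, and Col1a1 (-3.01) and C1qb (-2.03) in the library filed as R412X-R412X. In the library filed as R412X-Irf8 the macrophage median changed sign with doublets left out and with at least 200 UMIs.

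Xist, from the sex list, had at least 2 UMIs in 1721 of 1805 K403R cells, the library labelled female. In wild-type, labelled male, 20 of 3804 cells (0.526%, 0.321 to 0.811) had at least 2 Xist UMIs and no UMI from the Y chromosome, with a median of 8735.5 UMIs per cell. Genes within 5 Mb of Gfi1 passed 1.5-fold in 14.3%, 14.0% and 15.8% of cases in R412X-Het, the library filed as R412X-Irf8 and the library filed as R412X-R412X, against 12.3%, 12.2% and 11.2% of genes elsewhere. In Gfi1+/- none of 53 such genes did, against 1.42% elsewhere, and in K403R 5.77% did, against 3.43%. Myo18b in that window had log2 ratios of 2.76, 3.28 and 2.31 in the 3 R412X libraries, and Mfsd7a of 1.08, 1.78 and 1.12. Tesc, Sdsl, Myl10 and Mtus2, named above, lie on chromosome 5 like Gfi1 but outside the window. The comparison therefore does not cover them.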
